A study of Arabidopsis thaliana with 11 samples.

How the data were processed

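The data are the signals of 11 Affymetrix ATH1 arrays of Arabidopsis siliques in 8 crosses, 1 array for each of 5 crosses and 2 for each of 3. The deposited values are MAS5 signal intensity values on a linear scale, made with MAS5 in GCOS per the submitters' processing notes, and versions are not given in the sources used here. RNA was purified on columns and labelled with biotin in 1 cycle, per the labels' protocols. Because the 2% trimmed mean is 100.01 on every array, the scaling was kept and no further normalization was applied. MAS5 subtracts mismatch signals, so values near the floor are noisy, and for them the ratio of groups is unstable.

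A platform annotation named 1 gene for 13513 of 22810 probe sets and several for 503, and 8794 (controls included) were unnamed in it. Probe sets with several genes were tested but not named. Gene IDs of 13436 probe sets were found in the gene table of assembly TAIR10.1, which gave current symbols and the gene class. No coordinates are printed because the build behind the array is not given in the sources used here. Of 18 gene lists fixed before the data were examined, 4 had 3 or more tested genes, 9 had 1 or 2, and 5 had 0.

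Control probe sets (64) were left out, and a probe set was tested if it reached 20 (20% of the trimmed mean) on 2 or more arrays, which left 17196. Values were analysed as log2(signal + 10), so fold changes of dim genes are understated. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend in the variance and Benjamini-Hochberg adjustment at 0.05. The dosage slope used the 5 C24 arrays. The reciprocal met1 comparison and fis1 x 2x against met1 x 2x used the 6 arrays of the duplicated crosses. The 3 comparisons with 2x x 2x used all 11 arrays with a mean for each cross. Lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the brightest. Single arrays were described by differences of 2-fold or more and by list medians among 10000 random lists matched on mean expression.

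The genes named were chosen by a rule fixed before the data were examined: MET1, MEA and FIS2; for 5 comparisons, the 10 largest rises and 10 largest falls among called probe sets with 1 gene, filled up to 5 per direction with the largest changes at an unadjusted p under 0.01 where fewer passed; and up to 4 members of each list. Other genes are named only where said to be chosen after their values were seen.

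The tests were run on simulated data with 200 changed probe sets in 20 repeats. Where simulated spreads followed limma's own model, between 4.40% and 6.15% of calls were false. Where they followed limma's moderated spreads, the estimates from the duplicated crosses pulled towards the intensity trend, between 7.57% and 11.3% were false. The adjusted p-values here may therefore be somewhat too small, and which spreads apply was not tested. Moderated spreads vary less between probe sets than unmoderated ones, so recovery with them may be overstated. For the reciprocal met1 comparison, 8.41%, 79.4% and 96.0% of log2 changes of 1, 2 and 3 were recovered with the moderated spreads, and 1.29%, 48.1% and 80.7% with those of the model. For fis1 x 2x against 2x x 2x these shares were 2.35%, 58.7% and 91.5% with the former and 0.833%, 18.7% and 64.3% with the latter. The first version of this check, a single draw with a limit on the number of false calls, was not passed. The repeats, the second set of spreads and the criterion that replaced that limit were chosen after that outcome.

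Alternatives were other pseudocounts, filters and scalings, no variance trend, each array left out, the replicate number as a block, other reference arrays and other dosage terms. Some further alternatives and the gene classes were chosen after the data were seen. The levels of MET1, MEA and FIS2 under another scaling were not run, since these genes were not named.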

Results

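Gene expression was measured in Arabidopsis siliques collected 5 days after fertilization, on 11 ATH1 oligonucleotide arrays covering 8 crosses. Crosses are written with the seed parent first, the usual convention, which the labels do not state. Within the C24 accession, 5 crosses changed the ploidy of the parents. The 2x x 2x cross was balanced. Read in that order, 6x x 2x and 4x x 2x carried an excess of maternal genomes, and 2x x 4x and 2x x 6x of paternal genomes. Each of these 5 crosses had 1 array. The other 3 crosses had 2 arrays each: met1 x 2x and 2x x met1, the reciprocal crosses with a knockout of the maintenance DNA methyltransferase in the Col-0 background, and fis1 x 2x, with a mutant of the Polycomb gene MEA in the Ler-0 background as one parent. The mutants therefore differ from C24 in accession as well as in the mutated gene.

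The arrays had been scaled to a common level, and each had a trimmed mean signal of 100.01. Median signals lay between 38.0 and 43.9, and between 61.9% and 67.2% of probe sets reached the floor of 20 used for testing. Log2 values of any pair of arrays correlated across 17196 probe sets with r between 0.85 and 0.95. The most alike pair was the 2 arrays labelled 2x x met1. The replicates of met1 x 2x correlated at 0.91 and differed 2-fold or more at 1673 probe sets, those of fis1 x 2x at 0.91 and 1575 probe sets, and those of 2x x met1 at 0.95 and 916 probe sets. Only the arrays labelled 2x x met1 had their own replicate as the closest array once each probe set was centred on its mean. The spike-in transcript CreX ranged from 2031 in 2x x met1 replicate 1 to 13269 in 2x x met1 replicate 2. The 3′ actin control was 357 in fis1 x 2x replicate 2 and between 1706 and 2328 in the other arrays. The ratio of the 3′ to the 5′ actin control was 0.561 in fis1 x 2x replicate 2 and between 2.45 and 4.44 in the others. The 25S rRNA control ranged from 138 in met1 x 2x replicate 1 to 2617 in 2x x met1 replicate 2. RNA quality may therefore differ between arrays, and no comparison was adjusted for it. The small number of arrays limits the precision of every comparison, and p-values measure the spread between these samples, since the labels do not say that they came from separate plants.

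MET1, MEA and FIS2 were to be read first, as a check of the mutants. In the annotation used, 0 probe sets named any of these genes alone, so their levels were not analysed here and the labels have no check from the mutated genes.

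The reciprocal met1 crosses were compared to ask whether the parent that transmits the mutation matters. Transcripts of the pseudogene class, which in the annotation used takes in genes of transposable elements, were far higher in the arrays labelled 2x x met1 than in met1 x 2x. AT2G12300 reached signals of 3132 and 5281 in the arrays labelled 2x x met1 against 5.45 and 3.55 in met1 x 2x, a log2 change of -8.14 ± 1.11 (SE, n = 2 per cross) for met1 x 2x with an adjusted p of 0.023 in limma. AT3G30396, AT2G12240, AT2G10640, AT3G31955, AT2G13160, AT2G13870, AT2G12980 and AT3G47320, all pseudogene class, had log2 changes between -8.11 and -6.06. Of these 9 genes, only AT3G47320 has a probe set designed for a single transcript, and the others share theirs with related sequences. The protein-coding gene AT1G58025 was lower in met1 x 2x, with signals of 1.72 and 2.14 against 1537 and 1885, and had the smallest adjusted p, 1.0e-04. Signals so far under the floor of 20 make the sizes of these changes imprecise. In all, 119 probe sets differed in limma, 105 lower and 14 higher in met1 x 2x. Among those naming 1 gene, 76 of the 89 lower probe sets belonged to the pseudogene class, of which 250 were tested, and 0 of the 7 higher ones did. The class made up 79.2% of the called probe sets with 1 gene and 2.59% of those tested (Fisher's exact test, two-sided, p = 1.4e-106, a class chosen after the data were seen and whose probe sets are not independent). Its median log2 change was -1.05, against 0.02 for 9348 protein-coding probe sets. Among 20 annotation classes and gene families tested with camera after the data were seen, the pseudogene class had an adjusted p of 5.7e-54, and adjusted p = 0.0026 with an estimated correlation. A probe set could pass the filter through the 2 arrays labelled 2x x met1 alone. Of the 76 members called, 8 and 6 reached the floor of 20 in the met1 x 2x arrays. The tested share, the median and the p-values of the class may therefore depend in part on the filter, and the class was not counted without it.

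**Figure D1:**
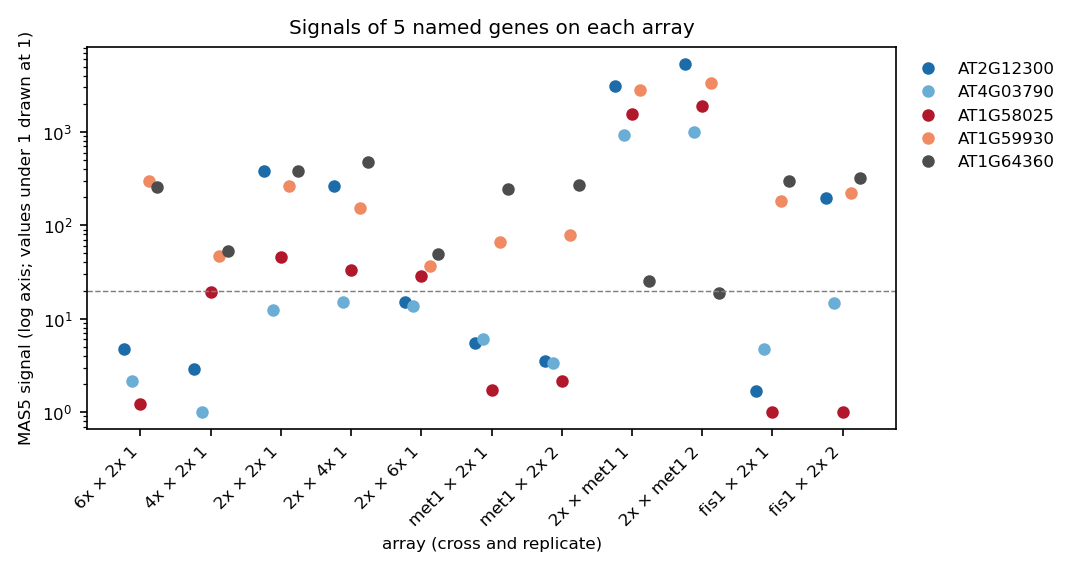
MAS5 signal (log axis, values under 1 drawn at 1) of 5 genes on each of the 11 arrays, 1 point per array; the dashed line is the testing floor of 20. AT2G12300, AT4G03790, AT1G58025 and AT1G59930 are highest in the 2 arrays labelled 2x x met1, and AT1G64360 is lowest there.

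Genes higher in met1 x 2x were fewer and changed less. AT1G64360 had signals of 246 and 273 in met1 x 2x and of 25.6 and 19.1 in the arrays labelled 2x x met1, a log2 change of 3.07 ± 0.22 (SE, n = 2 per cross; limma adjusted p = 0.0010). AT3G45160, AT1G62660, the glycosyl hydrolase gene BGLU40, AT1G68600, AT1G73600 and AT1G57620 were higher with log2 changes between 1.62 and 2.14. The mitotic kinase gene AUR2 was lower in met1 x 2x by -1.77 ± 0.26 (limma adjusted p = 0.035), while the other tested member of the mitotic list, AUR1, had a log2 change of -0.60 and did not pass. Of 15 tested type I MADS-box genes, 9 had positive and 6 negative changes. None passed over all probe sets, and AGL80, a regulator of the central cell, was the 1 member called when adjusted over the list alone, at 1.40 ± 0.32. QQS, which is silenced by DNA methylation, had signals of 1187 and 1382 in the arrays labelled 2x x met1 and of 5.33 and 326 in met1 x 2x. Its log2 change of -4.17 ± 1.18 did not pass over all probe sets (limma adjusted p = 0.39) and passed adjusted over the list alone (adjusted p = 0.017 in limma, 2 list genes). Without 2x x met1 replicate 1 the count of 119 became 24, without replicate 2 it became 17, and without met1 x 2x replicate 1 it became 67. In simulated data with the moderated spreads, 8.95% of the calls of this comparison were false, more than the nominal rate. With spreads that followed limma's own model, 4.40% were false.

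The arrays labelled 2x x met1 were set against the balanced 2x x 2x cross. AT4G03790 had signals of 936 and 994 against 12.5 in 2x x 2x, a log2 change of 5.44 ± 0.42 (SE, n = 2 against 1; limma adjusted p = 0.013). AT3G33066, AT1G36470, AT1G34530, AT2G12520, AT3G47260, AT1G42360 and AT2G06430, also of the pseudogene class, rose with log2 changes between 2.97 and 5.43, and the protein-coding AT1G58025 and AT1G59930 rose by 4.95 and 3.49. The probe sets of AT1G59930 and of 6 of these 8 pseudogene-class genes are shared with related sequences. AT1G64360 was the 1 lower call, at -3.60. Of 17 called probe sets 16 were higher, and 11 of these belonged to the pseudogene class. With the mean of the 5 C24 arrays as the reference, 161 were higher and 44 lower. The spread among those 5 crosses does not enter the error of that fit, so the larger count is not stronger evidence. AT4G01140, AT1G23200, AT1G50290 and AT4G33600 had log2 changes between -3.77 and -2.99 and did not pass. Of the fixed lists with 3 or more tested genes, none shifted (limma's camera, smallest adjusted p = 0.18). QQS and AUR2 had log2 changes of 4.26 and 1.06, and each passed adjusted over its list alone but not over all probe sets. The replication gene PRL (MCM7) had a log2 change of 0.96 with an unadjusted p of 0.0092 in limma. Its list has 1 tested gene, so no list adjustment applies, and it did not pass over all probe sets. The lone 2x x 2x array is assumed to vary like the duplicated crosses, and 0 probe sets passed without either array labelled 2x x met1. Leaving out an array of another cross gave 33, 32, 44 and 42 calls in place of 17 (without met1 x 2x replicates 1 and 2 and fis1 x 2x replicates 1 and 2).

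The met1 x 2x cross was set against 2x x 2x to follow the mutation as inherited from the parent written first, read as the seed parent. Limma called 0 probe sets, and 544 had an unadjusted p under 0.05, fewer than the 859.8 that chance gives on average. The largest positive changes at an unadjusted p under 0.01, none of which passed, were those of AT1G16950 at 3.00, AT1G32920 at 2.30, the ubiquitin ligase gene PUB19 at 2.28, AT2G20560 at 2.17 and AT4G13630, which was 4.28-fold higher, an imprecise value because its signal in 2x x 2x was 3.28. The largest negative ones were the pseudogene-class AT3G30396, AT2G12300, AT2G13160, AT2G10640 and AT2G12980, between -4.84 and -3.76. These transcripts had signals between 151 and 593 in the 2x x 2x array itself. The type I MADS-box genes shifted upward as a list, with 14 of 15 changes positive and a median of 0.74 (camera adjusted p = 0.0040), but adjusted p = 0.35 with an estimated correlation. Its members AT4G36590 (AGL40), AT5G26630 (AGL35), AGL61 and AGL29 had log2 changes of 1.89, 1.65, 1.02 and 0.95, imprecise because all 4 were under the floor in 2x x 2x, and 0 members were called over all probe sets or adjusted over the list alone. Under quantile normalization 12 of the 15 changes were positive. The median log2 difference of the list from 2x x 2x was 1.13 in met1 x 2x replicate 1 and 0.20 in replicate 2. Without met1 x 2x replicate 1 the count was 2, and without either fis1 x 2x array it was 3.

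The fis1 x 2x cross was set against 2x x 2x to ask which genes respond to a mutant Polycomb gene. Limma called 0 probe sets, with 868 at an unadjusted p under 0.05. The largest positive changes, none of which passed, were AT4G33980 at 3.52 ± 0.56 (SE, n = 2 against 1), AT1G61500 at 3.20, the cold-regulated gene COR27 at 2.93, AT1G52810 at 2.89 and AT4G29200 at 2.88. The largest negative ones were the pseudogene-class AT2G13160, AT2G12980, AT2G04000, AT1G43840 and AT1G33130, between -4.52 and -2.77. Of the 76 members of this class called between the reciprocal met1 crosses, 38 reached the floor in 2x x 2x and 40 in 2x x 4x. The count was 9 and 15 in the fis1 x 2x arrays and 12 in 6x x 2x. These falls may therefore come from the single 2x x 2x array and not from fis1. The 3 tested photosynthesis genes were lower as a list (camera adjusted p = 0.048), and adjusted p = 0.65 with an estimated correlation. RCA, the activase of Rubisco, had a log2 change of -1.10, SBPASE of the Calvin cycle -0.74 and the antenna gene LHCB4.1 -0.31, and 1 of these 3 changes was positive under quantile normalization. The list median was -0.34 in replicate 1 and -1.13 in replicate 2, the array in which the 3′ actin control was 357. The type I MADS-box genes had 13 of 15 positive changes and a median of 0.44, with 11 of 15 positive under quantile normalization, and the list did not shift (camera adjusted p = 0.26). Its median difference from 2x x 2x was 1.09 in replicate 1 and -0.02 in replicate 2. Its members AT4G36590 (AGL40), AGL33 and AT5G26630 (AGL35) had log2 changes of 1.92, 1.36 and 1.34, imprecise because all 3 were under the floor in 2x x 2x and in replicate 2. PRL, the single tested gene of its list, had a log2 change of 0.76 with an unadjusted p of 0.027 in limma and did not pass over all probe sets. Without fis1 x 2x replicate 1 the count was 11, and without replicate 2 it was 4.

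Fis1 x 2x and met1 x 2x were also compared directly. Limma called 0 probe sets, with 1534 at an unadjusted p under 0.05, more than the 859.8 that chance gives on average. Probe sets are not independent, so such counts can vary widely, and 1534 is not evidence of a difference. AUR1 and AUR2 had log2 changes of 0.94 and 0.72, and both passed when adjusted over the list alone but not over all probe sets. RCA had a change of -1.05 and COR15A of -0.87. Without fis1 x 2x replicate 1 the count was 44, without met1 x 2x replicate 1 it was 7 and without met1 x 2x replicate 2 it was 1.

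Across the 5 C24 crosses, the trend on the log2 ratio of pollen-parent to seed-parent ploidy asked which transcripts follow the parental dosage. Limma called 0 of 17196 probe sets, and 566 had an unadjusted p under 0.05, fewer than the 859.8 that chance gives on average. The largest positive slopes, none of which passed, were those of AT1G19960 at 0.93 ± 0.20 per unit of the log2 ratio (SE, 5 arrays), the expansin gene EXPB3 at 0.93, AT1G20070 at 0.87, AT1G65490 at 0.86 and AT2G47880 at 0.82. The largest negative slopes were those of UBC31 at -0.96, AT2G34890 at -0.89, AT3G56520 at -0.85, AT5G38960 at -0.80 and AT1G14580 at -0.70. The signal of EXPB3 was 93.4 in 6x x 2x, 149 in 4x x 2x, 213 in 2x x 2x, 313 in 2x x 4x and 1146 in 2x x 6x. The type I MADS-box genes AGL80, AGL57, AGL87 and AGL91 had slopes between -0.55 and -0.44, while 7 of the 15 members were positive and 8 negative with a median of -0.06, and no list shifted (camera, smallest adjusted p = 0.14). In simulated data with the moderated spreads of the duplicated crosses, 96.1% of slopes of 1 were recovered, and 85.3% with spreads drawn from the fitted model. These simulations held no differences between crosses other than dosage, which the 5 single arrays may have. They therefore do not show how many slopes of that size could be found here, and the 0 calls do not show that dosage has no effect.

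Single interploidy arrays were described against the single 2x x 2x array, with no replicate check and no test. The 2x x 4x array differed 2-fold or more at 1214 probe sets, 6x x 2x at 1420, 2x x 6x at 1999 and 4x x 2x at 2287. The type I MADS-box genes stood apart in crosses of opposite dosage: their median difference was 2.52-fold in 4x x 2x, with 14 of 15 higher, and 2.30-fold in 2x x 6x, with 12 of 15 higher. Of the 15 genes, 2 reached the floor of 20 in 2x x 2x, against 12 in 4x x 2x and 12 in 2x x 6x, so the sizes of these differences are imprecise. These medians lay at the percentiles 100 and 99.99 among 10000 random lists matched on mean expression. In 6x x 2x the median log2 difference was 0.51 (percentile 94.8) and in 2x x 4x it was -0.13 (percentile 16.6). The 3 maternally expressed imprinted genes MPC, UCL1 and AGL28 had median log2 differences of 1.42 in 4x x 2x (percentile 99.6) and 1.61 in 2x x 6x (percentile 99.5). All 3 were under the floor in 2x x 2x, which makes these values imprecise too. The signal of MPC was 158 in 4x x 2x, 269 in 2x x 6x, 19.2 in 2x x 2x, 10.2 in 2x x 4x and 5.01 in 6x x 2x. The photosynthesis genes had a median of 0.49 in 2x x 4x, at percentile 94.8, and of 0.12 under quantile normalization. The endosperm regulators IKU1, AGL61, AGL62 and AGL80 went both ways, with 2 of 4 higher in 4x x 2x and 2 of 4 in 2x x 6x. Their median log2 difference was 0.63 in 4x x 2x (percentile 96.9) and 0.90 in 2x x 6x (percentile 97.9). AGL61, AGL62, AGL80 and AGL28 are also in the type I MADS-box list, so these lists are not independent of it. The signal of AGL62 was 44.3 in 4x x 2x, 53.5 in 2x x 6x and 7.39 in 2x x 2x, and that of AGL80 was 17.8, 4.06 and 45.5.

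**Figure D2:**
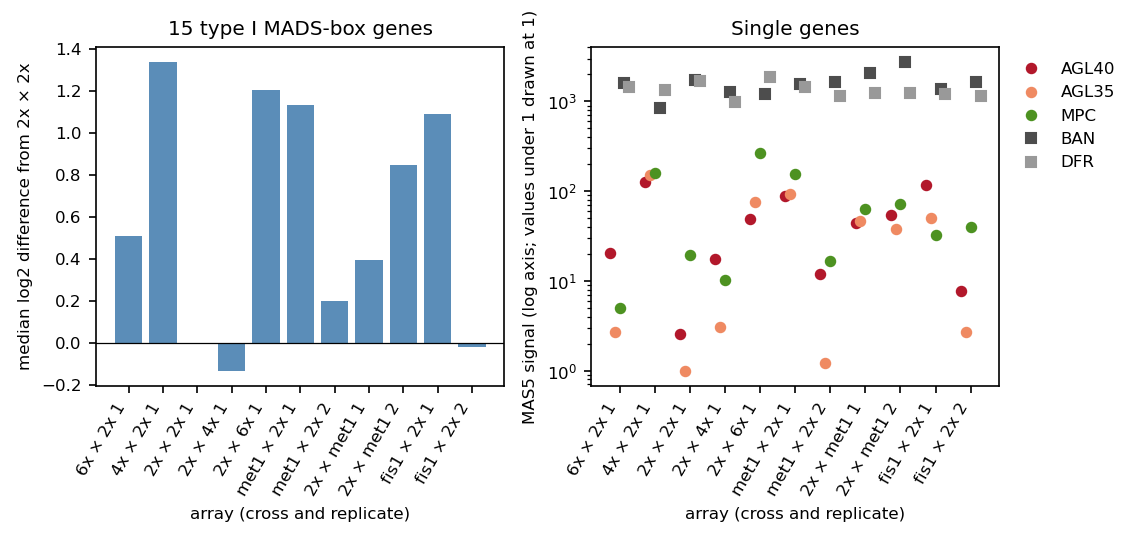
Left, bars give the median log2 difference from the 2x x 2x array of 15 type I MADS-box genes on each array; right, MAS5 signals (log axis, values under 1 drawn at 1) of AGL40, AGL35, MPC and the seed coat genes BAN and DFR, 1 point per array. The list median is 2.52-fold in 4x x 2x and 2.30-fold in 2x x 6x, with 2 of the 15 genes at or above the floor of 20 in 2x x 2x, and in met1 x 2x its log2 value is 1.13 in replicate 1 and 0.20 in replicate 2.

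The remaining fixed lists had 1 or 2 tested members, too few for a set test. In the reciprocal met1 comparison the seed coat flavonoid genes BAN and DFR had log2 changes of -0.57 and 0.05, the demethylase gene DME -0.27, the replication gene PRL (MCM7) -0.40, the carpel genes ALC and SPT -0.00 and 0.37, the pollen tubulin gene TUA1 0.04, the cold-induced genes COR15A and COR47 -0.34 and 0.33, and the paternally expressed AT4G11940 (ADM) -0.01. None of these passed over all probe sets or adjusted over the list alone. The lists of Polycomb, seed maturation, embryo patterning, seed coat mucilage, and gibberellin and auxin synthesis genes had 0 tested members.

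Agreement between comparisons was measured across genes, which are not independent replicates. The dosage slopes and the reciprocal met1 changes, which share 0 arrays, had a Pearson r of -0.00 and a Spearman rho of 0.03. The dosage slopes correlated with the fis1 x 2x changes at -0.20. The changes of met1 x 2x and 2x x met1, both against the 2x x 2x array, correlated at 0.52, those of fis1 x 2x and met1 x 2x at 0.51, and those of fis1 x 2x and 2x x met1 at 0.35. Simulated crosses without any effect gave 0.67 for each of these 3 pairs because of the shared array. The observed covariances less the simulated ones were 0.025, -0.0063 and -0.020. No probe set could be called in both members of any of these pairs, since at most 1 of the 2 comparisons had calls.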

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

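The direct comparison of the reciprocal met1 crosses was fixed before the data were examined, and the tests of explanations in this part were chosen after the results were seen. The crosses labelled as reciprocal for met1 differed: limma called 119 probe sets between met1 x 2x and the arrays labelled 2x x met1, of which 76 belonged to the pseudogene class, and AUR2 had a log2 change of -1.77.

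The high pseudogene-class signals are in the arrays where the mutant is labelled as the second parent. Probe sets matching several related sequences do not account for all of it, since 30 of 162 tested members that end in _at, which are designed for a single transcript, were called (Fisher's exact test, two-sided, p = 2.9e-42), although 35 of 51 ending in _x_at were. That p-value has the same limit from the filter as the test of the whole class. Array brightness does not account for it, since the spike-in CreX differed 6.53-fold between the 2 arrays. Exchanged parents or labels cannot be told apart from the labelled cross: 0 probe sets named MET1, MEA or FIS2 alone, and no marker of accession was tested. A met1 pollen parent also stays open, since QQS was at least 20.7 times its 2x x 2x signal in both arrays, as either reading would give. In met1 x 2x QQS was 5.33 and 326, against 57.3 in 2x x 2x. In the arrays labelled 2x x met1, 80 probe sets outside this class lay 2-fold or more above all 5 C24 arrays and 32 below. In met1 x 2x these counts were 3 and 0. If most silique tissue is of the seed parent, these values lean towards exchanged parents, but effects of the pollen parent were not separated from this. The accession of the parents is confounded with the mutation and was not tested. Which parent is written first also bears on fis1 x 2x and on the direction of the dosage trend, and was not tested there.

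The same transcripts were present at lower levels in further arrays: of the 76 members, 38 reached the floor in 2x x 2x and 40 in 2x x 4x, with median signals of 9.34% and 8.04% of those in the arrays labelled 2x x met1, against 15 in fis1 x 2x replicate 2, 12 in 6x x 2x, 12 in 2x x 6x and 3 in 4x x 2x. RNA carried over from a 2x x met1 sample is a candidate explanation that was tested with 2 measures in turn, and no biological explanation was tested. The first, the SD of the log2 share in 2x x 2x over the 38 members, was 0.739 against 0.471 between the arrays labelled 2x x met1, with shares between 3.99% and 48.1%; its bound had been set with the value in view, so it was set aside. The measure that replaced it took the 1063 other probe sets at 500 or more in both arrays labelled 2x x met1. Of these, 2 were under 2% of that signal in 2x x 2x, ECS1 at 0.118% and AT2G30810 at 0.162%. Both are far below the median share of the 76 members, 9.34%, which weighs against carry-over at that share. The lowest share, 3.99%, comes from members picked for reaching the floor in 2x x 2x, so lower shares were left out of it. In 2x x 4x, ECS1 was at 568 and AT2G30810 at 2.65. The rate at which replicate arrays differ as far was taken from probe sets with signals between 43.2 and 93.3. That range was predicted from the lowest share and has the same limit. Over all 1063 probe sets it would give 3.19 such values. That is likely too high, since it treats all of them as that dim in 2x x 2x. Only 8 were under 10% there, and over those 8 it would give 0.024. Carry-over was left open because the 2 values come from 1 array and only AT2G30810 was also that low in 2x x 4x. The 8 were also chosen after they were seen.

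The type I MADS-box genes split the arrays within met1 x 2x and fis1 x 2x as well as between crosses. The list differed between replicates by a median of 0.86 in log2 signal in met1 x 2x and 0.87 in fis1 x 2x. In each, 11 of 15 genes were higher in replicate 1. Between the arrays labelled 2x x met1 the median was 0.03, at percentile 41.3 among random lists. Array brightness does not account for the split within met1 x 2x and fis1 x 2x, where the CreX ratios were 0.985 and 0.912. The differences in these 2 crosses lay at percentile 99.99 or above among random lists matched on mean expression, also under quantile normalization, where they were 0.87 and 0.84. RNA quality was not tested as a cause. The ratio of 3′ to 5′ actin was 4.44 and 2.71 in met1 x 2x replicates 1 and 2, and 2.74 and 0.561 in those of fis1 x 2x. It was 4.42 in 2x x 4x, where the list was low. Parental dosage stays open although the lower of the list's percentiles in 4x x 2x and 2x x 6x was 99.99, because these crosses of opposite dosage had 1 array each and arrays of 1 cross differed as well. A smaller share of seeds would lower seed coat genes by as much as the list, and only BAN and DFR were tested among them. Their differences were -0.09 and 0.32 between the met1 x 2x arrays, and -0.26 and 0.05 between the fis1 x 2x arrays. None was as large as the list's difference, which argues against this explanation for BAN and DFR. It stays open because 2 genes are too few to exclude it. The stage or amount of endosperm may be the cause and cannot be told apart from the explanations left open, because only 1 tested endosperm regulator lies outside the MADS family.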

How the results depend on the processing

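Alternatives chosen after the data were seen are the probe sets ending in _at, the 4 other C24 arrays as the reference and the paired removal of C24 arrays. None of the 1009 alternative values of 63 named gene results reversed direction; 845 stayed on their side of the threshold, 140 no longer passed and 24 newly passed. For the reciprocal met1 comparison (119 calls), a pseudocount of a smaller size gave 74, probe sets ending in _at gave 47, and leaving out an array gave between 17 and 136. For the arrays labelled 2x x met1 against 2x x 2x (17 calls), the smaller pseudocount gave 3, the larger one 69, no filter 7, the stricter filter 4, no variance trend 51, the mean of 5 C24 arrays as the reference 205 (161 higher and 44 lower), the 4 other C24 arrays 209 (165 higher and 44 lower), and leaving out an array between 0 and 44. For fis1 x 2x against 2x x 2x (0 calls), both other references gave 1 and leaving out an array between 0 and 11; for met1 x 2x against 2x x 2x the latter gave between 0 and 3, and for fis1 x 2x against met1 x 2x between 0 and 44. With several C24 arrays as the reference, the spread among their crosses does not enter the error, which may raise the count. The cause was not tested in any of these.

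The dosage trend had 0 calls under every alternative fixed before the data were examined, each array left out included (range 0 to 0). Leaving out 4x x 2x and 2x x 6x together gave 662. These arrays were picked because they looked alike, 1 residual degree of freedom remained, and of the 10 ways to leave out a pair the next highest gave 28 and 8 gave 0, so this count is not evidence of a trend. Of the 24 gene results that newly passed, those of the dosage trend did so only there.

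The labels do not say that the replicate number pairs samples of different crosses. The replicate differences of met1 x 2x and fis1 x 2x correlated at 0.37, and those of 2x x met1 correlated with them at 0.05 and 0.02. With the replicate block the arrays labelled 2x x met1 against 2x x 2x had 7 calls, the reciprocal met1 comparison 123, and the other comparisons with 2x x 2x and fis1 x 2x against met1 x 2x had 0.

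Both list calls were lost with an estimated correlation (0 calls; adjusted p of 0.35 for the MADS-box genes in met1 x 2x and 0.65 for photosynthesis in fis1 x 2x) and with fry (adjusted p of 0.45 and 0.59). Fry, which does not compare a list with other genes, called 3 others, the endosperm regulators in the reciprocal met1 comparison (0.019), met1 x 2x against 2x x 2x (0.039) and fis1 x 2x against met1 x 2x (0.010). The larger pseudocount lowered the 2-fold counts of single arrays to 255 in 2x x 4x, 851 in 2x x 6x, 1164 in 4x x 2x and 472 in 6x x 2x. The levels of MET1, MEA and FIS2 under quantile normalization were not run. Signals near the floor limit what can be said of dim genes.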

Other observations

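Tests in this part were chosen after the results were seen, as were the genes named. Further transcripts divided the arrays across crosses and within duplicates. AT2G30810 had signals of 4209 in 4x x 2x, 3632 in 2x x 6x and 4131 in met1 x 2x replicate 1, but of 1.75 in 2x x 2x and 2.65 in 2x x 4x. AT3G24510, the defensin-like gene LCR24 and the expansin gene EXPA21 had signals of 4532, 1048 and 839 in 4x x 2x. In met1 x 2x, AT3G24510 had 1552 in replicate 1 and 8.30 in replicate 2, and EXPA21 had 1203 and 1.78. AT5G38160 and AT5G38170 ran the other way, with 51.6 and 229 in 4x x 2x and 4154 and 5949 in 2x x 2x. The first principal component of all tested probe sets held 22.6% of the variance and placed met1 x 2x replicate 1 at -23.1 and replicate 2 at 27.1. ECS1 had signals of 2367 and 2311 in the arrays labelled 2x x met1 and of 2185 in met1 x 2x replicate 2, but of 11.2 in met1 x 2x replicate 1.

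One hypothesis was that the probe sets at an unadjusted p under 0.05 in the dosage trend reflect chance. The trend had 566 of them, and 39 of 60 arrangements of the 5 dosages over the arrays gave as many, the real one included, so chance cannot be excluded. The highest other arrangement gave 1987, several times the real count, which may reflect a structure of the samples other than dosage, and no such structure was tested; 7 arrangements had calls at the adjusted threshold, the most being 143, and the real one had 0.

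In both arrays labelled 2x x met1, 88 pseudogene-class probe sets lay 2-fold or more above all 5 C24 arrays, against 0 in met1 x 2x and 0 in fis1 x 2x. Of other probe sets, 80 lay above and 32 below in the arrays labelled 2x x met1, 3 and 0 in met1 x 2x, and 5 and 8 in fis1 x 2x.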
